A study of Drosophila melanogaster with 16 samples.

How the data were processed

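The series measured RNA in the heads of Drosophila melanogaster flies aged 10 days. Per the labels' protocols, each sample pooled 6 flies, heads were dissected from frozen flies, and ribosomal RNA was depleted before stranded libraries were made and sequenced as paired ends. All flies carried the glial and the neuronal driver. Control flies carried no α-synuclein, and the glia, neuron and both flies carried it under the glial, the neuronal or both systems. Samples were grouped by their titles and genotypes. The labels give 4 samples per group in 4 batches, and the batch equals the replicate number. The table held columns for 13 of the 16 samples (3 control, 3 glia, 3 neuron, 4 both), and the 3 others (control 4, glia 3 and neuron 4) were not used here. No label gives a reason, and had they been left out for their values, the spread of their groups would be understated in every test.

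The submitters' processing notes name FastQC, STAR, Salmon, featureCounts, MultiQC and DESeq2 and the genome build BDGP6, without versions, settings or an annotation release. The deposited values are a signal derived from read counts, called adjusted counts per the file headers. From the values themselves, each is 1 plus a read count divided by a factor that is fixed within a column. After 1 was subtracted and the factor undone, 100% of values were whole within 0.01 (largest distance 2.4e-05), which gave the reads per library. The group mean columns equalled the means of their samples within a relative gap of 7.2e-10 and were not used otherwise. How the submitters chose the 12286 genes of the table is not stated. Symbols came from the table, and 12147 of its gene IDs (98.87%) were also found in the reference gene name table. Coordinates came from an Ensembl annotation of BDGP6 by gene ID.

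Normalized counts were the deposited values minus 1. This reading was chosen after the offset had been seen, and the values with their offset kept were run as an alternative. The design written before the data were examined had a count test as its first choice and limma-trend for normalized values. The second was used because the deposited values are not whole counts, although the reads recovered from them would have allowed the first. Genes with a normalized count of at least 1 in at least 4 samples were tested (12181, with 105 removed). A linear model with the 4 groups and no batch term was fitted to log2(normalized count + 1) of all 13 samples with limma 3.58.1 in R 4.3.3 (limma-trend, 9 residual degrees of freedom), and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The 7 comparisons were the 6 pairs of groups and the interaction. With 3 samples against 3, a permutation test of a single value cannot go below p = 0.1, so the tests share one estimate of the spread across all groups. Simulated data from the real means, with genes drawn independently of each other, were used to check the fit. For glia against control, 56 of 100 genes changed 2-fold and 91 of 100 changed 4-fold were recovered, with 4 false calls among 151 in 12196 genes. For both against control the values were 58, 90 and 10 among 158 in 12188 genes, and for both against glia 50, 88 and 9 among 147 in 12183 genes. Only genes above a minimum mean were changed. The simulation had no RNA shared unequally by many genes, so it does not tell how many false calls that would bring.

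The 31 gene lists were fixed before the data were examined and were tested with camera at a preset correlation of 0.01, adjusted over the lists. A list needed 3 tested members, which left out the list of male-linked dosage compensation RNAs with 1. List genes were matched by the table's symbols or by current symbols, a widening made after a first look at which genes matched. No list call in any comparison held when the correlation was estimated from the data. Limma's fry was run beside camera. The 8 organ marker lists were written after the values had been seen, and a list of held-out organ genes was written before their values were looked up.

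The naming rule, fixed in advance, took the largest changes past the threshold with a mean of at least 5 CPM and the same direction against the same-batch sample in all batches available, up to 10 per direction against control and up to 5 for the other comparisons. For the interaction it had no batch condition. It took the 5 smallest p-values where no gene passed, and up to 4 members with the smallest p of each list described. Genes named outside this rule are said to be so, and organ markers and the genes compared by batch were chosen after their values had been seen.

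Because the labels give a batch for each number, numbers pair the samples by label. Deviations from the group means of same-batch samples of different groups had a median correlation of 0.07 over 16 pairs, with 5 above 0.1. A batch holds at most 1 sample of a group, so a difference within 1 batch has no replicates to test it, and a fit with batch as a block (6 residual degrees of freedom) took its place. Fits also set before the data were examined were this block, other pseudocounts, no or a stricter filter, a fold threshold, fits to the compared groups alone, and leaving out each library or each batch. Those chosen after the data were seen were voom on the whole reads, scaling to library totals, centring each library on the median of the neuronal markers, 3 covariates for accessory gland, ovary and midgut marker levels, leaving out control 1 and glia 2, and the values with their offset. The organ covariates differ between the groups themselves, and the fit with them has 6 residual degrees of freedom. It can separate group from organ RNA only in part, so lost calls and turned directions in it do not show a cause. Centring moves all genes of a library alike, so a list whose sign turns with it keeps its place among the other genes. Count tests and normalizations that need a table of counts were not run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.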

Results

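RNA was sequenced from the heads of 10-day-old fruit flies with human wild-type α-synuclein, the presynaptic protein that aggregates in Parkinson's disease, in glia, in neurons, in both cell types or in neither. Glial expression used the pan-glial Repo driver of the GAL4 system, and neuronal expression used the Synaptobrevin driver of the Q system, so that either could be switched on alone. Each sample was a pool of 6 flies, 3 males and 3 females, so a replicate is a pool and not a single fly. The table held 3 control, 3 glia, 3 neuron and 4 both libraries, and the remaining 3 samples of the series were not analysed here. Reads in genes numbered 3072254, 3705086 and 2808960 in control 1, 2 and 3, and 3125791, 3419829 and 3235216 in glia 1, 2 and 4. They numbered 4176009, 4158972 and 3741323 in neuron 1, 2 and 3, and 3060727, 4400688, 4767799 and 3828547 in both 1, 2, 3 and 4. The 10 most abundant genes took 8.92% to 14.5% of a library, and mitochondrially encoded genes took 2.94% to 8.02%. Values are normalized counts, given as mean ± SD, with n = 3 for control, glia and neuron and n = 4 for both. Fold changes are on the log2(normalized count + 1) scale, which understates the change of genes with low counts, and those of genes near 0 in a group depend on the added 1. Zero reads in every library of a group allowed a mean of up to 1.19 in control, 1.13 in glia, 0.92 in neuron and 0.72 in both, at 3 reads over the group and for counting error only.

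Transcripts typical of organs outside the head were at unequal levels in these libraries, as the plot of organ marker lists shows. The ejaculatory bulb proteins Peb and PebII had a median of 3503 normalized counts in control 1, 1431 in control 2 and 127 in control 3, against 11.5 or less in every neuron and both library. The 47 male accessory gland genes had library medians of 136, 14.2 and 37.1 in control and at most 1.8 in neuron and both. The 11 ovary and eggshell genes had a median of 378 in glia 2, against at most 29.9 elsewhere. Cyp4g1, the cytochrome P450 of hydrocarbon synthesis in oenocytes, averaged 8258 ± 7203 in control, 11569 ± 10107 in glia, 1165 ± 1292 in neuron and 146 ± 184 in both. The 105 tested genes of these 8 lists, which were written after the values had been seen, made up 1.14% of normalized counts in control 1, 1.09% in glia 2 and 0.01% in both 2 and both 3. They are given beside each gene group that they moved with.

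**Figure D1:**
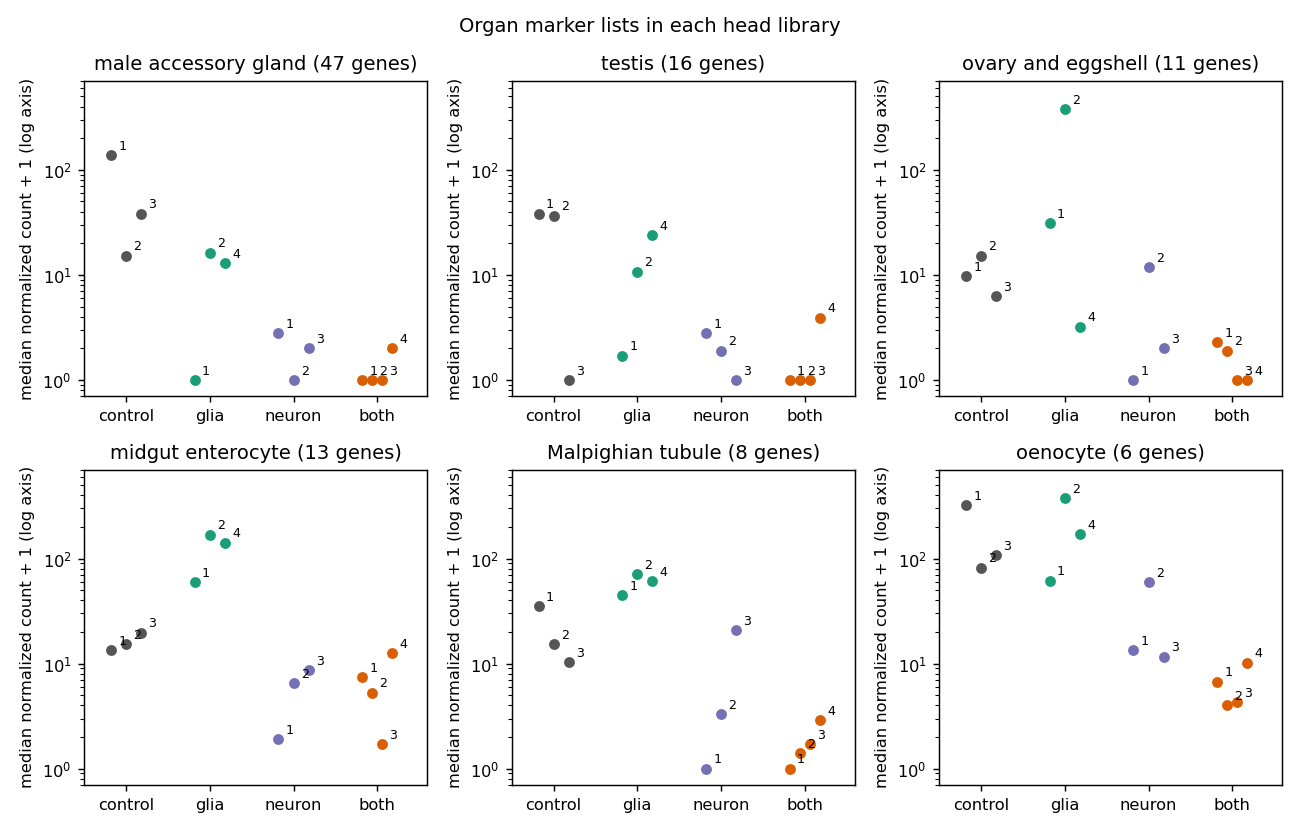
Median normalized count plus 1 of 6 organ marker lists in each of the 13 libraries, on a log axis, with each point a library numbered by its replicate. The accessory gland medians of the 3 control libraries lie above those of every neuron and both library. The midgut medians of the 3 glia libraries (58.5, 167 and 140) lie above those of all other libraries (18.6 at most).

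The comparison of glia with control addressed what α-synuclein in glia alone does to gene expression in the head. The 10 largest increases by the naming rule were in CG18404, CG5767, CG8661, CG5804, LysX, CG16775, CG15423, Vha100-4, CG14500 and thetaTry. LysX, which encodes a lysozyme, had 64.9 ± 36.2 in glia and 0.8 ± 1.4 in control (log2 fold 5.25, SE 0.66, adjusted p = 0.00294). Vha100-4, a subunit of the vacuolar proton pump, had 126.5 ± 41.1 and 5.0 ± 6.5 (5.06, SE 0.99, adjusted p = 0.0383). LysX (FBgn0004431) lies on chromosome 3L from 1194739 to 1195302 and Vha100-4 (FBgn0038613) on 3R from 18386841 to 18389805 of the fly genome build BDGP6. The trypsin gene thetaTry had 263.8 ± 184.5 in glia and 7.1 ± 4.6 in control (4.83, SE 0.96, adjusted p = 0.0408). Midgut enterocyte markers were higher in the same libraries, with medians of 58.5, 167 and 140 in glia and at most 18.6 in control. For LysX, Vha100-4 and thetaTry an effect of α-synuclein in the head cannot be told apart from unequal midgut RNA. Decreases were fewer and smaller. Obp56g, an odorant binding protein, fell from 456.5 ± 282.7 to 105.4 ± 14.9 (-1.88, SE 0.39, adjusted p = 0.0481). It had 737.8, 459.3 and 172.3 in control 1, 2 and 3, the same order as the ejaculatory bulb gene Peb (4151, 1908 and 167). Its fall cannot be told apart from unequal organ RNA in the controls. CG17325 fell from 184.8 ± 15.4 to 104.9 ± 17.1 (-0.82, SE 0.15, adjusted p = 0.0306). The third decrease, CG31680, lay outside the naming rule and was named after its values had been seen.

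Among the lists fixed before the data were examined, the odorant binding proteins were lower in glia. Their library medians were 48.1, 40.8 and 65 in glia 1, 2 and 4 and 74.4, 64.9 and 71.6 in control 1, 2 and 3. Glia 4 thus lay level with control 2. Of 37 tested members 34 had a negative fold change, with a median of -0.73. Over all genes 1 passed, and 12 passed when adjusted over the list alone (camera adjusted p = 6.84e-10, and adjusted p = 0.205 with an estimated correlation). The actin and spectrin cytoskeleton list was higher, with a median of 0.23. Its library medians were 356, 563 and 456 in glia 1, 2 and 4 and 325 to 372 in control, so that glia 1 lay among the controls and glia 2 stood apart. Of 21 members 3 rose over all genes and 8 rose adjusted over the list alone (camera adjusted p = 2.43e-08, and adjusted p = 0.122 with an estimated correlation). They were Arp2 of the actin-nucleating Arp2/3 complex (0.75, SE 0.12, adjusted p = 0.0137), the spectrin gene kst (0.50, SE 0.09, adjusted p = 0.0215) and the cytoplasmic actin gene Act5C (0.79, SE 0.15, adjusted p = 0.0333). With batch as a block their adjusted p was 0.0564, 0.122 and 0.0946. In limma's fry, which tests whether a list moves on balance one way, the odorant binding proteins had an adjusted p of 0.0075 and the actin and spectrin list 0.00326. All 24 gut digestive enzymes had a positive fold change (median 1.53), of which thetaTry passed over all genes and 3 passed adjusted over the list alone (camera adjusted p = 4.56e-05, and adjusted p = 0.661 with an estimated correlation). With organ marker covariates, midgut genes among them, the enzyme list turned lower (adjusted p = 0.000125). Their level differed between the glia libraries: Jon25Biii, a digestive protease, had 4587, 754.5 and 0 in glia 1, 2 and 4. Of the 13 midgut enterocyte markers 6 rose (list median 2.38), and Myo61F, a brush border myosin, had 560 ± 38.8 in glia and 125 ± 13.8 in control. Markers of the Malpighian tubule, the fly's excretory organ, had a median of 1.41 with 8 of 8 members positive and 0 past the threshold.

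A further 7 lists passed the list test. The proteasome subunits (median 0.17, 31 of 32 positive), the glutathione and oxidative stress genes (0.18), the cytochrome P450 and UDP-glycosyltransferase genes (0.13) and the cell cycle genes (0.49) were higher, with camera adjusted p of 0.00017, 0.00483, 0.0118 and 0.00434. They had adjusted p = 0.77, 0.316, 0.661 and 0.77 with an estimated correlation. The cell cycle genes had their highest library median, 172, in glia 2, the library with the most ovary RNA. It was 44.9 and 22.8 in glia 1 and 4 and 31.1 to 70.1 in control, so the rise rested on glia 2. The proteasome median was 294 in glia 2 but 189.9 and 182 in glia 1 and 4, inside the control range of 172 to 199. Olfactory and gustatory receptors (median -0.39), photoreceptor genes (-0.25) and cytosolic ribosomal proteins (-0.12) were lower. Camera adjusted p was 0.000923, 0.00644 and 4.56e-05, and adjusted p = 0.267, 0.773 and 0.77 with an estimated correlation. The ribosomal list lost its call with batch as a block (adjusted p = 0.0966). When libraries were centred on neuronal markers, photoreceptor genes had -0.08 and ribosomal proteins 0.04, both below the median of all genes (0.14). Receptor library medians were only 2 to 3.7 normalized counts in these groups. The receptor list had -0.61 with a pseudocount of 0.1 and -0.17 with one of 5. Photoreceptor medians of 1139 and 1194 in glia 1 and 4 lay within the control range of 1051 to 1332, and only glia 2 was lower (716). Library medians of the groups overlapped in 8 of the 10 lists that passed in this comparison.

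In limma's test 94 genes differed between glia and control, 91 higher and 3 lower, and 90 by voom on whole reads, all higher. With batch as a block the count was 29, all higher, of which 25 were among the 94. Of the genes named by the rule, LysX (adjusted p = 0.0391) and Vha100-4 (adjusted p = 0.034) passed while the others had adjusted p from 0.0564 to 0.215. The count was 37, 55 and 52 without control 1, 2 or 3 and 60, 30 and 131 without glia 1, 2 or 4. It was 0 without batch 1. Without both control 1 and glia 2, the libraries with the most organ RNA, it was 9, and with 3 organ marker covariates it was 0.

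**Figure D2:**
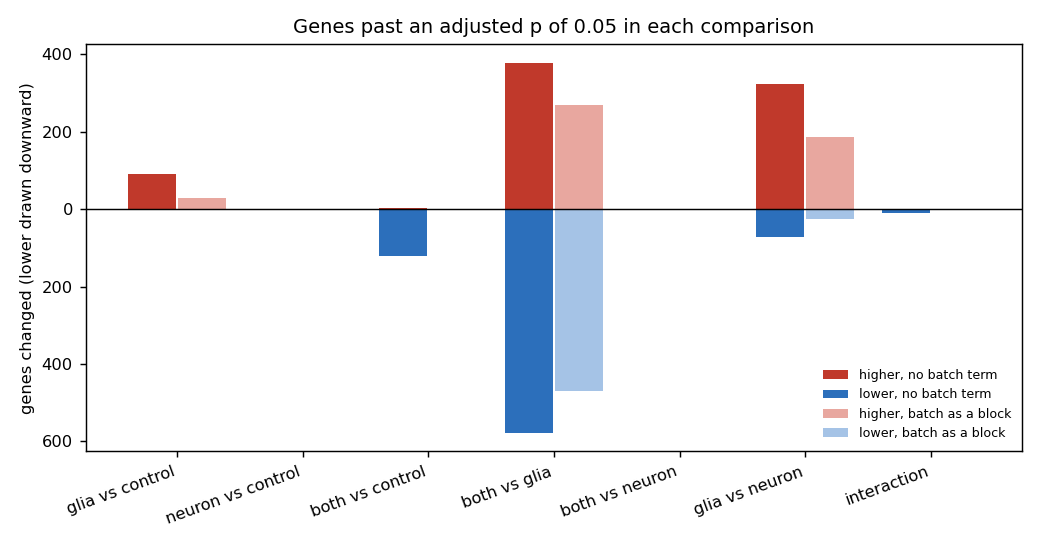
Number of genes past an adjusted p of 0.05 in each comparison, with bars up for higher and down for lower genes, from limma without a batch term and with batch as a block. The largest counts are 379 higher and 578 lower for both against glia (268 and 471 with the block), and the 120 lower genes of both against control become 1 with the block.

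The comparison of neuron with control addressed α-synuclein in neurons alone. No gene passed. The 5 smallest p-values were all for lower values in neuron libraries and belonged to CG17472, CG42852, BG642163, CG18869 and CG11598, each with an adjusted p of 0.0954. CG42852 had 282.9 ± 233.4 in control and 0.6 ± 0.5 in neuron (-6.75, SE 1.14), and BG642163 had 114 ± 81.1 in control and no read in neuron, at least 124-fold lower at the floor of 3 reads over the group. At an unadjusted p under 0.05 limma counted 1502 genes, where 609 were expected by chance, and voom on whole reads called 0. The count was 86 without control 2 and 254 without control 3, and 0 without any other single library.

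As lists, photoreceptor and phototransduction genes were higher in neuron (27 of 28 positive, median 0.51, or 0.12 when libraries were centred on neuronal markers), with 1 member passing adjusted over the list alone. Neuronal markers were higher by a median of 0.39 (24 of 25 positive), by construction near 0 after that centring (-0.01). Camera adjusted p was 8.65e-15 and 9.27e-08, and adjusted p = 0.682 with an estimated correlation for both lists. Both lists turned lower in neuron with organ marker covariates (adjusted p = 0.00282 and 0.0019). The accessory gland median was at most 1.8 in neuron and at least 14.2 in control. Group and covariates are thus hard to separate in this fit, and the turn does not show a cause. The opsin gene ninaE, the main visual pigment, had 74038 ± 13453 in neuron and 46398 ± 2326 in control. Neuropeptides (median 0.26, with NPF at 0.67, SE 0.17, and Crz at 0.87, SE 0.27), circadian clock genes (0.17), olfactory and gustatory receptors (0.18) and glial markers (0.20) were also higher. Centred on neuronal markers these had -0.14, -0.22, -0.22 and -0.20, still above the median of all genes after that centring (-0.45). Muscle markers (median -0.48), gut digestive enzymes (-2.03), cytosolic ribosomal proteins (-0.16) and proteasome subunits (-0.19) were lower. For these 8 lists the adjusted p ran from 1.98e-05 (neuropeptides) to 0.0321 (glial markers) and, with an estimated correlation, from adjusted p = 0.682 to adjusted p = 0.889. With the covariates the proteasome list turned higher (adjusted p = 5.72e-07). No single member of any of these lists passed over all genes, and library medians of the groups overlapped in 2 of the 10 lists. The male accessory gland list had a median of -4.23 and the oenocyte list of -2.95 in the same comparison.

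Expression in both cell types was compared with control to see the joint effect. Transcripts of the male reproductive tract led the decreases. CG17097 averaged 736.1 ± 578 in control and had no read in any both library (at least 1020-fold lower at the floor of 3 reads over the group). Peb fell from 2076 ± 1997 to 4.7 ± 8.8 (-8.80, SE 1.70, adjusted p = 0.0332), and the seminal fluid gene Sfp60F from 885 ± 1030 to 1.0 ± 1.9 (-8.08, SE 1.54, adjusted p = 0.0315). The other named decreases were Mst57Db, PebII, Mst57Da, CG43147 (at least 733-fold lower), CG31872, Acp95EF and Sfp87B, with adjusted p from 0.0239 to 0.0332. Of all 120 lower genes 35 belonged to the organ marker lists, 24 of them to the accessory gland. The 3 genes that rose were the eye pigment enzyme gene se (29.4 ± 4.4 to 67.4 ± 11.2; 1.16, SE 0.20, adjusted p = 0.024), boss, the photoreceptor ligand of the Sevenless receptor (246 ± 18.0 to 462 ± 43.1; 0.90, SE 0.17, adjusted p = 0.03), and the perilipin gene Lsd-1 of lipid droplets (815 ± 50.8 to 1429.5 ± 98.5; 0.81, SE 0.12, adjusted p = 0.0229). The gene boss (FBgn0000206) lies on chromosome 3R from 25961994 to 25966948, and Lsd-1 (FBgn0039114) on 3R from 23763857 to 23766662.

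Photoreceptor genes were higher in both as a list (27 of 28 positive, median 0.61, or 0.15 when centred on neuronal markers). No member passed over all genes and 21 rose adjusted over the list alone (camera adjusted p = 7.16e-15, and adjusted p = 0.657 with an estimated correlation). Neuronal markers were higher by a median of 0.51 (camera adjusted p = 2.67e-10, and adjusted p = 0.657 with an estimated correlation), or 0.05 after that centring. Both lists turned lower with organ marker covariates (adjusted p = 0.00874 for photoreceptor genes and 0.029 for neuronal markers). Nuclear-encoded genes of oxidative phosphorylation were lower, with a median of -0.52 and 78 of 81 members negative. None of them passed over all genes, while 54 fell and 1 rose adjusted over the list alone (camera adjusted p = 6.76e-16, and adjusted p = 0.657 with an estimated correlation). Muscle markers were lower in 18 of 18 members (median -1). The myosin light chain gene Mlc2 passed over all genes (-0.90, SE 0.18, adjusted p = 0.0372, or 0.0968 with batch as a block) and 16 passed adjusted over the list alone (camera adjusted p = 1.88e-08, and adjusted p = 0.657 with an estimated correlation). In these groups control 3 had the highest library median for muscle markers (3074) and for oxidative phosphorylation genes (608). Both 1 had the lowest for each list (789 and 318). Whether the muscle and oxidative phosphorylation lists fell separately was not tested. Antimicrobial peptides and Bomanins, the effectors of fly humoral immunity, had a positive fold change in 19 of 26 members (median 0.61, or 0.15 when centred), with library medians of 62.3 to 169.8 in control and 99.7 to 212 in both and none past the threshold (camera adjusted p = 0.00221, and adjusted p = 0.743 with an estimated correlation). Gut digestive enzymes (median -2.22), proteasome subunits (-0.20) and cytosolic ribosomal proteins (-0.13) were lower. Neuropeptides (0.30), glial markers (0.14), cuticle proteins (0.21) and olfactory and gustatory receptors (0.11) were higher. These 7 lists had camera adjusted p from 0.00219 to 0.0408, and adjusted p = 0.657 to 0.743 with an estimated correlation. When centred on neuronal markers, the 4 higher lists were negative, while the median of all genes was -0.51. After that centring muscle markers had -1.46, oxidative phosphorylation genes -0.98 and proteasome subunits -0.66. Under the batch block the proteasome (adjusted p = 0.111) and ribosomal (adjusted p = 0.137) lists lost their calls. The proteasome list turned higher with organ marker covariates (adjusted p = 8.13e-07) and neuropeptides turned lower (adjusted p = 0.0105). Library medians of the groups overlapped in 7 of the 12 lists. The cuticle and receptor lists had medians of at most 8 normalized counts in every library, so their fold changes depended on the added 1. Alongside, oenocyte genes had a median of -5.02 with 5 of 6 past the threshold.

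In limma's test 123 genes differed between both and control, 3 higher and 120 lower, while voom on whole reads called 0 and 2379 genes had an unadjusted p under 0.05. With batch as a block 1 gene passed, v(2)k05816 (adjusted p = 0.0393), named after its values had been seen, and the 13 genes named by the rule had adjusted p from 0.0599 to 0.0685. The count was 0 without control 1 or without both 1, 4 without both 2, 1 without both 3 and 556 without control 3. It was 0 without control 1 and glia 2 and 0 with organ marker covariates. The balance of directions depended on the fit: 394 higher and 298 lower when only these groups were fitted, and 657, all lower, when libraries were centred on neuronal markers.

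The comparison of both with glia asked what neuronal α-synuclein adds to glial α-synuclein, and it gave the largest number of differences in the fit of all 4 groups, though not in fits of the compared groups alone (288, against 692 for both with control). The largest increases were in Obp56e, an odorant binding protein (68.4 ± 33.2 to 284 ± 68.9; 2.15, SE 0.42, adjusted p = 0.0107), Nplp3, a neuropeptide-like precursor (254 ± 116 to 710.5 ± 197; 1.54, SE 0.35, adjusted p = 0.0218), CG11391, the corneal lens protein gene retinin (373 ± 152 to 1032 ± 299; 1.52, SE 0.33, adjusted p = 0.0164) and CG17386. The largest decreases were in Muc11A, a mucin gene (899 ± 234 to 0.2 ± 0.5; -9.54, SE 1.05, adjusted p = 0.000441), CG31198, CG31343, CG31233 and the mucin-related gene Mur18B (433 ± 93.2 to 2.9 ± 5.2; -7.63, SE 1.27, adjusted p = 0.00423). In the same libraries the midgut enterocyte list had medians of 58.5, 167 and 140 in glia and at most 11.6 in both. Obp56e (FBgn0034471) lies on chromosome 2R from 19712345 to 19712932 and Muc11A (FBgn0052656) on X from 12059795 to 12065144.

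Photoreceptor genes were higher in both than in glia: 19 of 28 rose over all genes, and 27 rose and 1 fell adjusted over the list alone, with a median of 0.87 (0.25 when centred on neuronal markers). Rhodopsin genes were among them, Rh6 at 1.00 (SE 0.20, adjusted p = 0.0126), Rh4 at 1.00 (SE 0.20, adjusted p = 0.0126) and Rh3 at 0.93 (SE 0.19, adjusted p = 0.0142). Neuronal markers were higher by a median of 0.62, or 0 after centring. Of 25 members 5 rose over all genes and 22 adjusted over the list alone, led by nSyb, a synaptic vesicle protein (0.78, SE 0.19, adjusted p = 0.0306). The photoreceptor and neuronal lists had camera adjusted p of 2.11e-15 and 4.8e-10, and adjusted p = 0.393 with an estimated correlation each. Each turned lower in both with organ marker covariates (adjusted p = 0.00322 and 0.0368). Odorant binding proteins were higher by a median of 0.76, or 0.14 when centred. Of 37 members 13 rose over all genes and 16 adjusted over the list alone, among them Obp56d (1.26, SE 0.20, adjusted p = 0.00322) and Obp28a (1.29, SE 0.23, adjusted p = 0.00581). The actin and spectrin list was lower by a median of -0.39, with glia 1 (356) inside the library range of both (301 to 368) and glia 2 (563) apart. Of 21 members 9 fell over all genes and 14 adjusted over the list alone, led by Act5C (-0.89, SE 0.14, adjusted p = 0.00341) and the actin-capping gene cpa (-0.64, SE 0.12, adjusted p = 0.00663). These had camera adjusted p of 1.28e-08 and 5.47e-05, and adjusted p = 0.169 with an estimated correlation each.

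**Figure D3:**
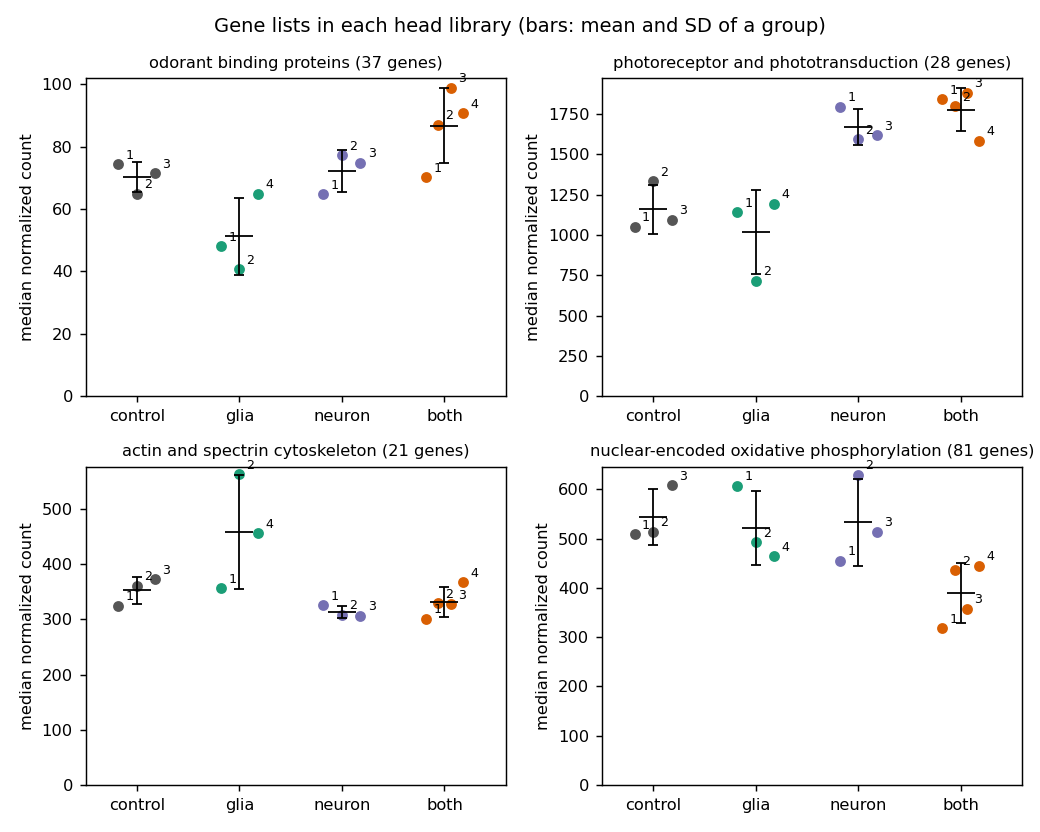
Median normalized count of the members of 4 gene lists in each library (points numbered by replicate), with bars for the mean and SD of each group. Odorant binding protein medians are 40.8 to 65 in glia and 70.3 to 98.9 in both, and the photoreceptor medians of the glia libraries (716 to 1194) lie below those of all neuron and both libraries (1582 and above).

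Gut digestive enzymes were lower in both than in glia in 24 of 24 members (median -4.25), and 6 fell over all genes and 11 adjusted over the list alone (camera adjusted p = 1.95e-07, and adjusted p = 0.393 with an estimated correlation). Library medians were 1303, 421 and 65.0 in glia 1, 2 and 4 and 49.2, 11.5, 0 and 157 in both, so that glia 4 lay below both 4. In the carbohydrate metabolism list 5 of 32 fell over all genes and 12 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0111, and adjusted p = 0.483 with an estimated correlation). Its leading members, Mal-A4 (-4.59, SE 0.49, adjusted p = 0.000401), Mal-A2, Mal-A3 and Mal-A7, encode maltases. Proteasome subunits were lower in 32 of 32 members (median -0.40; 2 over all genes, 18 adjusted over the list alone), with glia 2 (294) apart and glia 4 (182) next to both 3 (181), and nuclear-encoded oxidative phosphorylation genes in 76 of 81 (median -0.43; 2 over all genes, 25 adjusted over the list alone). These had camera adjusted p of 7.11e-07 and 3.34e-08, and adjusted p = 0.421 with an estimated correlation each. Oxidative phosphorylation medians were 607, 492 and 464 in glia 1, 2 and 4 and 318 to 445 in both. Glia 1 also had the highest muscle median of these groups (2787), and both 1 the lowest (789). Cell cycle genes (median -1.08), muscle markers (-0.80), mitochondrially encoded genes (-0.54), mitochondrial ribosomal proteins (-0.26) and heat shock proteins (-0.20) were also lower. Cell cycle medians were 44.9, 172 and 22.8 in glia 1, 2 and 4 and 19.8 to 21.2 in both, with glia 2 apart. Mitochondrially encoded genes had 8751, 3856 and 4751 and 3470 to 4470, with glia 1 apart and glia 2 inside the range of both. Fat body markers (0.65, or 0.03 when centred on neuronal markers), neuropeptides (0.36), circadian clock genes (0.26), glial markers (0.21), olfactory and gustatory receptors (0.50), cuticle proteins (0.45) and antimicrobial peptides (0.41) were higher. The last 6 of these were negative after that centring, though above the median of all genes (-0.7). The cell cycle list turned higher with organ marker covariates (adjusted p = 0.0368). For these 12 lists camera adjusted p ran from 3.23e-06 (receptors) to 0.0321 (heat shock proteins), and with an estimated correlation from adjusted p = 0.101 to adjusted p = 0.669. Library medians of the groups overlapped in 9 of all 20 lists that passed. Alongside, 10 of 13 midgut markers, 6 of 8 Malpighian tubule markers and 6 of 6 oenocyte markers fell. The lowest value of nSyb in any library, 1360, was in glia 2, against 2248.5 and 2800 in glia 1 and 4.

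In limma's test 957 genes differed between both and glia, 379 higher and 578 lower; all 10 genes named by the rule also passed with batch as a block. The count was 427 without glia 2, 1876 without glia 4, 469, 480 and 460 without both 1, 2 or 3, and 342 without control 1 and glia 2. It was 116 without batch 2. With organ marker covariates it was 0. Centring on neuronal markers gave 12 higher and 2879 lower, and the fit of these groups alone 34 higher and 254 lower.

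The comparison of both with neuron asked what glial α-synuclein adds to neuronal α-synuclein, and no gene passed in the fit of all groups, while 5 did when only these groups were fitted and 2 with organ marker covariates. The smallest p belonged to fit, a fat body gene that responds to feeding, with 1227 ± 506 in both and 319 ± 87.0 in neuron (1.89, SE 0.30, adjusted p = 0.369). CG8157, CG34134, Obp49a and the wing selector gene vg followed, each with an adjusted p of 0.761. Antimicrobial peptides and Bomanins were higher in both in 25 of 26 members (median 0.89), with library medians of 44.8, 35.9 and 129.7 in neuron and 212, 206, 99.7 and 112 in both, so that neuron 3 lay above both 3 and both 4. The leading members were AttC at 2.18 (SE 0.56), IM2 at 1.40 (SE 0.43), IM23 at 2.10 (SE 0.66) and IM1 at 1.39 (SE 0.46). None passed over all genes or adjusted over the list alone (camera adjusted p = 3.27e-12, and adjusted p = 0.534 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes were lower in 72 of 81 members (median -0.36), and 14 fell adjusted over the list alone (camera adjusted p = 1.11e-29, and adjusted p = 0.534 with an estimated correlation). Their library medians were 455, 629 and 514 in neuron 1, 2 and 3 and 318 to 445 in both. Neuron 2 also had the highest muscle median of these groups (2380), and both 1 the lowest (789). Muscle markers (median -0.49), mitochondrially encoded genes (-0.31), carbohydrate metabolism genes (-0.22) and mitochondrial ribosomal proteins (-0.16) were lower. Fat body markers (0.26), odorant binding proteins (0.14), neuronal markers (0.09), endoplasmic reticulum stress genes (0.08) and Toll and Imd pathway genes (0.06, or 0 when centred on neuronal markers) were higher. For these 9 lists camera adjusted p ran from 8.72e-06 to 0.0464, and with an estimated correlation from adjusted p = 0.534 to adjusted p = 0.822. Under the batch block the neuronal (adjusted p = 0.391) and endoplasmic reticulum (adjusted p = 0.0536) lists lost their calls. Library medians of the groups overlapped in 9 of the 11 lists. The oenocyte list had a median of -1.95 in the same comparison. At an unadjusted p under 0.05 limma counted 516 genes, where 609 were expected by chance, and voom called 0.

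Glia and neuron, the single-expression genotypes, were compared directly to test whether their profiles differed from each other. Higher in glia were CG18404 (380 ± 191 in glia and no read in neuron, at least 414-fold at the floor of 3 reads over the group), CG5767, CG31233, CG10912 (adjusted p = 0.0161, or 0.0633 with batch as a block) and thetaTry. Lower in glia were CG9497 (129.9 ± 41 against 383 ± 45.6; -1.60, SE 0.22, adjusted p = 0.00182), Obp28a (73.5 ± 29.1 against 180 ± 5.8; -1.37, SE 0.25, adjusted p = 0.00907), CG8401 (adjusted p = 0.037, or 0.116 with the block), Jhedup, a juvenile hormone esterase relative (-1.29, SE 0.26, adjusted p = 0.0162), and Obp69a (-1.29, SE 0.29, adjusted p = 0.0336). The actin and spectrin list was higher in glia (median 0.47), led by Act5C (1.11, SE 0.15, adjusted p = 0.00173). Of 21 members 8 rose over all genes and 14 adjusted over the list alone. Library medians were 356, 563 and 456 in glia 1, 2 and 4 and 306.5 to 325.5 in neuron, with glia 2 apart. Odorant binding proteins were lower (median -0.26), with 6 of 37 past the threshold over all genes and 14 adjusted over the list alone. Photoreceptor genes were lower too (median -0.79), 5 of 28 over all genes and 26 adjusted over the list alone. When centred on neuronal markers the medians were 0.30 and -0.23, both below the median of all genes (0.61). These 3 lists had camera adjusted p of 5.87e-07, 7.62e-06 and 1.86e-15, and adjusted p = 0.126, 0.317 and 0.317 with an estimated correlation. Olfactory and gustatory receptors were lower (median -0.50, or 0.06 after centring), with Orco, the shared co-receptor of odorant receptors, at -1.24 (SE 0.28, adjusted p = 0.0326, or 0.053 with the block). The list had a camera adjusted p of 1.15e-07, and adjusted p = 0.0883 with an estimated correlation.

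Gut digestive enzymes (median 4.22), cell cycle genes (1.02), proteasome subunits (0.37, with glia 2 apart), endoplasmic reticulum stress genes (0.26) and glutathione genes (0.17) were higher in glia than in neuron. Neuropeptides (-0.37), circadian clock genes (-0.31), glial markers (-0.26) and cuticle proteins (-0.34) were lower. Centred on neuronal markers they were positive, though below the median of all genes (0.61). Neuronal markers were lower (-0.53), by construction near 0 after centring (0.03). The cell cycle median of glia 4 (22.8) lay inside the neuron range of 19.1 to 30.0, while that of glia 2 (172) stood apart. For these 10 lists camera adjusted p ran from 5.3e-08 to 0.0344, and with an estimated correlation from adjusted p = 0.161 to adjusted p = 0.499. With organ marker covariates the photoreceptor and neuronal lists turned higher in glia (adjusted p = 0.00106 and 0.00196) and the cell cycle list lower (adjusted p = 0.0433). Library medians of the groups overlapped in 7 of all 14 lists that passed. Midgut markers stood beside them, with 8 of 13 higher in glia. In limma's test 395 genes differed, 324 higher in glia and 71 lower; with batch as a block 212 did (186 and 26), of which 183 were among the 395. The count was 24 without batch 1, 175 without glia 2, 1189 without glia 4, 139 without neuron 1, 138 without control 1 and glia 2, and 0 with organ marker covariates.

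Changes against the shared control libraries were also set side by side across all 12181 genes. The log2 fold changes of glia and neuron had a Pearson r of 0.22 and a Spearman rho of 0.15 across genes, which are not independent replicates, and 53.1% of genes had the same sign. In 100 simulations, unchanged groups and a control that they shared were drawn from deviations from the group means. The draws came from all libraries of all groups, with replacement and random sign, and did not keep the real controls. They gave a median r of 0.45 (the central 95% from -0.17 to 0.82) and a median of 66.7% with the same sign. The covariance was 0.134 and the simulated median 0.1, a difference of 0.035. At an adjusted p under 0.05 no gene was shared, and at 0.1 there were 2 shared lower genes, where lists of 22 and 11 drawn independently would share 0.02, a value that leaves out the shared controls, so the excess is no measure of a shared effect.

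The interaction, both minus glia minus neuron plus control, asked whether the joint effect differed from the sum of the single effects on the log scale. It was negative for 10 genes and positive for none. The 5 named by the rule were CG9568 (-4.83, SE 0.69, adjusted p = 0.0323), CG43349 (-4.54, SE 0.71, adjusted p = 0.0435), CG18493 (-3.82, SE 0.52, adjusted p = 0.0315), Tsp2A, a tetraspanin of septate junctions (-3.20, SE 0.49, adjusted p = 0.04), and CG9673 (-3.16, SE 0.37, adjusted p = 0.0186). CG18493 had 429 ± 137 in glia, 19.4 ± 7.0 in control, 5.5 ± 1.7 in neuron and 8.9 ± 3.5 in both, and Tsp2A had 90.8 ± 35.5, 16.2 ± 4.6, 14.4 ± 4.0 and 7.6 ± 2.0. Tsp2A is among the midgut markers, whose list median for the interaction was -2.64. Odorant binding proteins had a positive interaction in 33 of 37 members (median 0.93), none passing over all genes and 6 higher and 1 lower adjusted over the list alone (camera adjusted p = 3.15e-11, and adjusted p = 0.298 with an estimated correlation). Antimicrobial peptides had a median of 0.71 (camera adjusted p = 0.000472, and adjusted p = 0.646 with an estimated correlation), and the actin and spectrin list had -0.24 with 4 members lower adjusted over the list alone (camera adjusted p = 0.000111, and adjusted p = 0.34 with an estimated correlation).

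Negative list medians for the interaction were also found for nuclear-encoded oxidative phosphorylation (-0.32), mitochondrially encoded genes (-0.49), mitochondrial ribosomal proteins (-0.19), proteasome subunits (-0.20), carbohydrate metabolism (-0.33), gut digestive enzymes (-2.03), cell cycle (-0.44), heat shock proteins (-0.29), glutathione genes (-0.14) and autophagy and lysosome genes (-0.11). Positive medians were found for cytosolic ribosomal proteins (0.16, or -0.07 when centred on neuronal markers), photoreceptor genes (0.28, or 0.05 when centred), neuronal markers (0.22, or -0.01 when centred), fat body markers (0.69), cuticle proteins (0.34) and olfactory and gustatory receptors (0.27, or 0.04 when centred). With organ marker covariates the interaction turned positive for gut digestive enzymes (adjusted p = 0.000239), nuclear-encoded oxidative phosphorylation (adjusted p = 0.0133) and carbohydrate metabolism (adjusted p = 0.0168). For the 16 lists camera adjusted p ran from 1.58e-06 to 0.0468, and with an estimated correlation from adjusted p = 0.485 to adjusted p = 0.743. Under the batch block the cuticle list lost its call (adjusted p = 0.101). Single libraries stood apart in some of these lists. Glia 2 did for cell cycle (172, against 44.9 and 22.8 in glia 1 and 4) and proteasome (294, against 190 and 182). Mitochondrially encoded genes were highest in control 1 (8176) and glia 1 (8751). In limma's test 889 genes had an unadjusted p under 0.05 and voom called 0. With batch as a block 0 genes passed, and the 5 named genes had adjusted p from 0.1 to 0.138. The count was 0 without any of neuron 1, 2 or 3 or both 1, 2 or 3, 1 without control 2, 3 without control 3, 2 without glia 2 and 47 without glia 4. It was 2 without control 1 and glia 2 and 0 with organ marker covariates.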

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

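The tests of gut tissue, dilution, photoreceptor genes, α-synuclein effects on organ genes, heat stress and stock differences were chosen after the results they explain had been seen, while the splits of the samples and the held-out organ genes were set beforehand.

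Within the both group, 60 measures (named genes, each taken once, and list medians that reached 10 normalized counts, and reads per library) were tested for a library far from the other 3. Of these 8 were, all of them genes, where a rule passing about 1 in 20 by chance would give 3. In both 4, CG5767 had 24.1, CG8661 26.1 and thetaTry 12.5 normalized counts, against 0 in the other libraries of the group, where any value above 0 stands apart, so these 3 do not count beyond chance. Both 4 had the most organ marker RNA of its group (a sum of 1357, against 263 to 722) and a gut enzyme median of 157 (0 to 49.2). Mur18B had 10.6 in both 4 (at most 0.9 elsewhere in the group), Tsp2A 10.6 (6.4 to 6.8), CG9673 15.4 (9.7 to 10.2) and Obp56e 181.4 (311.7 to 326.3). Peb had 17.9 in both 1 and at most 1 in the others. Mur18B and Peb were thus also near 0 in the other libraries of the group and do not count beyond chance. The rate of 1 in 20 leaves out that some named genes were chosen as the largest decreases in both.

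In limma's interaction test 10 genes passed, 2 of them midgut markers. Unequal midgut RNA between the groups cannot be told apart here from an effect of glial α-synuclein that depends on neuronal α-synuclein. The log2 interaction was -4.83 for CG9568, -4.54 for CG43349, -3.82 for CG18493, -3.20 for Tsp2A, -3.16 for CG9673, -3.10 for CG9672, -2.45 for nub, -2.38 for CG9380, -1.83 for CG4301 and -1.12 for CG11961. All 10 were higher in every glia library than in any other library, and 0 of the 10 passed with batch as a block. The last 5 were named after their values had been seen. Of 100 random splits, the real one included, 2 gave as many genes as the real 10, and the highest other gave 460, several times more. Which libraries that split put together was not examined.

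The first pattern is that transcripts of abdominal organs were on average higher in control and glia than in neuron and both in each of the 8 organ lists, though single libraries overlapped (an ejaculatory bulb median of 2.6 in glia 1 and 11.5 in both 1), with midgut genes higher in glia than in control. RNA of abdominal tissue in the head samples may account for it: of 20 held-out reproductive tract and germline genes 95% were higher in control than in both (55.9% of all genes were). Gut tissue in the glia samples may account for the midgut genes, since the Malpighian tubule list, an organ joined to the gut, had a median log2 difference of 1.41 with 8 of 8 members positive. Whether the amount of gut was alike in these libraries stays open. The gut enzyme gene Jon99Fi was unequal (4237, 605 and 3.3 in glia 1, 2 and 4), while Myo61F (515 to 583) and the midgut marker mex1 (58.5 to 87.8) were even. An effect of α-synuclein on these genes in the head cannot be told apart from abdominal tissue as the cause of the group differences. The range among control libraries exceeded the difference between control and both in only 1 of the 8 organ lists, testis. Because the organ lists were written after the values had been seen, this is no test of a group difference. Genotype does not account for unequal levels within a group. Among glia libraries the ovary list ranged over 6.86 log2, with a difference of 1.21 from control. The midgut and Malpighian tubule lists ranged over 1.05 and 0.16, below their differences of 2.72 and 1.46.

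The second pattern is that photoreceptor and neuronal genes were higher in both than in control, though with organ covariates both lists turned lower (camera adjusted p = 0.00874 and 0.029). Those covariates differ between the groups themselves, so the turn does not show a cause. Dilution of head RNA by RNA of other organs is a candidate explanation: across the 13 libraries, deviations from the group means of photoreceptor level and of summed organ marker RNA had a Pearson r of -0.73 (permutation p = 0.0051, Benjamini-Hochberg adjusted 0.01) and a Spearman rho of -0.76 (permutation p = 0.0075), two-sided with 100000 resamples. The r was -0.67 without neuron 2 and both 4, the farthest on the organ axis, and -0.73 without glia 2, while for neuronal markers it was -0.47 (permutation p = 0.21, adjusted 0.21). Against it, organ markers summed to at most 1.14% of normalized counts, and the share of RNA that comes with them is not known. An effect on photoreceptor genes beyond that on neuronal genes cannot be told apart from none, since the difference between both and control was 0.55 (SE 0.09) before and 0.10 (SE 0.08) after subtraction of the neuronal mean, and an effect shared by both lists stays open.

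The third pattern is that the eye colour gene w and Hsp70Bb were higher in batches 3 and 4 than in batches 1 and 2. Heat stress is argued against, since the other 22 heat shock and chaperone genes had a median log2 difference of 0.02, with 20 of them below 1 and 0 past the threshold. The lowest value of w in batches 3 and 4 was 5.85 times its highest in batches 1 and 2, with the difference in all 4 genotypes, which restates the pattern and supports no cause. Transgene or stock differences between batches cannot be told apart from other differences between them, because no label gives the stocks of each batch.

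The counts of changed genes were set against other splits of the same libraries. For both against control the real 123 was the highest of 35 splits (1 of 35 gave as many, the highest other 1). For both against glia the real 957 was also (1 of 35, highest other 108). The splits left batch out of the fit. With batch as a block the real 123 became 1 and the real 957 became 739, and without control 1 the 123 became 0. For both against neuron (35 of 35, highest other 1) and neuron against control (10 of 10, highest other 1) the real count was 0, which every split reaches, so the splits say nothing about these. With 3 against 3 libraries the 10 splits are too few for a share under 0.05. There the real value and the highest other were 94 and 237 for glia against control (2 of 10 gave as many) and 395 and 0 for glia against neuron (1 of 10). The split with 237 put control 1, control 2 and glia 4 together, all 237 were higher there with 9 of 16 testis markers among them, and 132 had a mean under 1 in both, which points to a structure of the samples.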

How the results depend on the processing

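The fits with voom, library totals, centring, organ covariates, the kept offset and without control 1 and glia 2 were chosen after seeing the data, and all others were set before.

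With batch as a block, 29 genes passed for glia against control (94 without it), 1 for both against control (123), 212 for glia against neuron (395) and 0 for the interaction (10). For both against glia 739 passed (957), and the block changed no other count of genes. A pseudocount of 0.1 gave 26 genes for glia against control and 4 for the interaction, and one of 5 gave 179 and 43. With at least 1 CPM in at least 8 samples, 28 passed for glia against control, 14 for both against control and 256 for glia against neuron. Fits to only the compared groups gave 692 for both against control (394 higher), 288 for both against glia (34 higher), 5 for both against neuron and 145 for glia against neuron. At an adjusted p below 0.1, the changes of glia and neuron against control shared 2 genes, both lower, and 0 at 0.05. Controls were not split between these comparisons, as only 3 were used here, so part of the overlap of 2 may come from shared controls.

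Among the fits chosen later, voom gave 0 genes for both against control and 0 for the interaction, and the kept offset gave 19 for the interaction. Centring on neuronal markers gave 35 for glia against control, 657 for both against control, all lower, 2891 for both against glia (12 higher, 2879 lower), 512 for glia against neuron (509 higher, 3 lower) and 0 for the interaction. After centring the median of all genes was 0.14 for glia, -0.45 for neuron and -0.51 for both against control. That median was -0.70 for both against glia, -0.07 for both against neuron, 0.61 for glia against neuron and -0.22 for the interaction. With organ covariates 0 genes passed for glia against control, 0 for both against control, 0 for both against glia, 2 for both against neuron, 0 for glia against neuron and 0 for the interaction. Because the covariates differ between the groups themselves, the calls lost with them do not show that organ RNA was the cause. Without control 1 and glia 2 the counts were 9 for glia against control, 0 for both against control, 342 for both against glia, 138 for glia against neuron and 2 for the interaction.

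Leaving out each library or batch gave 0 to 131 genes for glia against control, 0 to 254 for neuron against control, 0 to 556 for both against control and 116 to 1876 for both against glia. It gave 0 to 0 for both against neuron, 24 to 1189 for glia against neuron and 0 to 53 for the interaction. The cause of these changes was not tested.

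With a correlation estimated for each list, 0 lists passed for glia against control, 0 for neuron against control, 0 for both against control, 0 for both against glia, 0 for both against neuron, 0 for glia against neuron and 0 for the interaction. With fry 2 passed for glia against control, 0 for neuron against control, 0 for both against control, 0 for both against neuron and 0 for the interaction, while 14 passed for both against glia and 10 for glia against neuron. With organ covariates 7 lists passed for both against glia, where 20 did without them, and 11 for glia against control (10), 9 for neuron against control (10), 10 for both against control (12), 10 for both against neuron (11), 10 for glia against neuron (14) and 13 for the interaction (19). Of the lists that passed without covariates, 4 of 10 changed direction with them for glia against control, 7 of 10 for neuron against control, 7 of 12 for both against control and 11 of 20 for both against glia. It was 0 of 11 for both against neuron, 10 of 14 for glia against neuron and 5 of 19 for the interaction. Among the 7 for both against glia, photoreceptor and neuronal genes had turned lower and cell cycle genes higher.

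The 60 results of named genes, some of them named in more than one comparison, include those of neuron against control and both against neuron. No gene passed there without a batch term, so those results had no call to lose. Weaker means here that a result past the threshold no longer passed. Of the 60, 30 were weaker with batch as a block, 47 with organ covariates and 34 with voom. Centring made 20 weaker, a pseudocount of 0.1 made 20 weaker, and 37 were weaker in at least 1 fit without a single library of the compared groups. Fits without a batch were not run for the named results. The CPM filter removed part of the 60, and of the rest 26 were unchanged and 4 were weaker. With organ covariates 1 was stronger and 3 changed sign in both against control, Mst57Db (0.14), CG31872 (0.01) and Acp95EF (0.62). No named result that passed without these covariates still passed with them.

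Count tests and the normalizations that go with them were not run on the deposited values, which are not whole counts. Apart from voom they were not run on the recovered reads either. Settings for the submitters' own comparisons did not apply.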

Other observations

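Several gene groups not yet described did not pass as lists without a batch term or covariates. The hemocyte markers, the JAK-STAT and Turandot stress genes, the lipid metabolism genes and the genes of JNK signalling and apoptosis passed camera in no comparison of that fit, with smallest adjusted p of 0.233 (both against glia), 0.301 (both against neuron), 0.0686 (both against control) and 0.382 (both against control). With batch as a block the lipid metabolism list passed for both against control (higher, adjusted p = 0.0117). With organ covariates the hemocyte list passed for glia, neuron and both against control (lower, adjusted p = 0.000618, 0.0192 and 0.029) and for the interaction (positive, adjusted p = 0.00155). Single lipid metabolism genes passed over all genes, 2 higher and 2 lower in both than in glia, 2 higher in glia than in neuron and 1 higher and 1 lower in both than in control, and 1 gene of the JAK-STAT list was lower in both than in glia. The feeding-responsive gene fit had an interaction of 2.56 (SE 0.44, limma adjusted p = 0.0646). The larval serum protein gene Lsp1beta was 2.33 (SE 0.70, limma adjusted p = 0.865) higher in both than in neuron.

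Some genes separated the batches in every genotype. The eye colour gene w averaged 303.5 normalized counts over the 8 libraries of batches 1 and 2 and 3621 over the 5 of batches 3 and 4 (log2 difference 3.64, SE 0.26, limma adjusted p = 3.49e-05), and Hsp70Bb averaged 94 and 5054 (6.32, SE 0.67, limma adjusted p = 0.00108). In limma's test with group in the model 41 genes differed between the batches, 31 higher and 10 lower in batches 3 and 4, among them the lactate dehydrogenase gene ImpL3 (61.4 and 747), MFS3 (14.9 and 155) and Dgp-1 (207 and 575). The receptor gene mthl8 had no read in either library of batch 4 and 70.3 to 218 normalized counts in the others. These genes and the grouping of batches were chosen after their values had been seen.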
